A study of Mus musculus with 7 samples.

How the data were processed

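The measurements were single-cell RNA libraries made from dissected uterine tissue of control mice and of Kdm6b cKO mice (cKO commonly abbreviates conditional knockout). Kdm6b encodes a histone lysine demethylase. Per the labels' protocols, minced tissue was kept frozen, digested with enzymes to free the cells, and samples needed at least 70% viable cells. Cells of each specimen were tagged with lipid-conjugated oligonucleotides (hashing), 125000 cells per specimen were pooled, 340000 cells were loaded per pool, and libraries were made with a droplet 3' kit and sequenced to 30000 reads per cell. Per the submitters' processing notes, Cell Ranger, Seurat and the mouse build mm10 were used; versions and settings are not given in the sources used here.

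The values analysed are the authors' annotation of each cell, without the expression of any gene. Per the file headers, it holds the UMI count and the gene count per cell as whole numbers that the authors did not normalize, and the count of hashing UMIs. The percent of UMIs from mitochondrial genes and from ribosomal protein genes was deposited per cell, with no value above 20% for the former. The authors also deposited an S and a G2M score per cell, a phase call made from them, and a 2-dimensional embedding. The score values reach down to -60.7 for the S score, the gene lists behind them are not stated, and only the phase calls were used. Cells had been filtered and assigned to specimens by the authors before deposit, by rules not given in the sources used here, and doublets were not called again. At most 4 hashing oligonucleotides had a UMI in any cell, while pools held 8 to 12 specimens, and every share rests on that assignment. The authors' Louvain clusters at 9 resolutions carry numbers and no names. Without gene values no marker could be read, so clusters stay unnamed here, the level of Kdm6b was not analysed here, and cells could not be thinned to an equal depth.

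A specimen is what the authors' assignment names, with the cells of its pools (repeat lanes of the same hashed mixture) added together. The 7 pools hold 28 specimens, 14 per genotype, in 3 experimental batches. Specimens and not cells were the replicates. Sites were not tied to a mouse by the annotation as used here, so no mouse entered a fit. Specimens of the different sites may come from the same mice, so the 13 pregnant specimens per genotype may not all be independent. For non-pregnant and day 5 inter-implantation specimens, each replicate pooled the uteri of 2 mice, per the labels. The names of the day 12 myometrium/endometrium specimens of batch 3 repeat a replicate number of batch 1, and whether mice were shared is not stated. A chi-square test over the coarsest clusters with at least 15 cells found that 6 of the 28 specimens differed between their own pools at an adjusted p under 0.05. The largest such difference was in the cKO day 12 myometrium/endometrium specimen of batch 1, where coarse cluster 4 took 13.3% and 24.5% of the cells in its pools.

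Cells per cluster and specimen were counted at resolution 2 (61 clusters). These counts were tested with edgeR 4.0.16 (R 4.3.3), with the quasi-likelihood F test, the specimen's total cells as library size and no composition factor. Clusters needed 10 cells on average per specimen, p-values were adjusted by Benjamini-Hochberg, and the threshold was 0.05. Standard errors are the log2 difference divided by the square root of F. Genotypes were compared over all 10 site-by-day strata with the stratum as covariate, and within each stratum from 1 fit with a mean per stratum and genotype. Strata with 1 specimen per genotype take their spread from the replicated strata. Sites were compared in control specimens with the day as covariate, and the slope on gestation day was tested in pregnant control specimens of each site. Specimen medians of UMIs, genes and mitochondrial percent, and the share of S and G2M calls, were compared by a two-sided permutation test within strata. The 30720 arrangements were sampled with 100000 draws (20000 where a specimen or pool was left out). Shares of single specimens have exact (Clopper-Pearson) 95% intervals, which cover counting error only.

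The design, the tests and most alternatives were fixed before the data were examined. Clusters are named where their adjusted p was under 0.05, up to 25 per comparison, together with the 5 largest by mean share (0, 1, 2, 3 and 4); any other cluster named was chosen after its values were seen. The comparison of non-pregnant with day 5 specimens had been planned as a test, but each arm held 1 control specimen, so it is given as values. The fits of each site alone, the genotype-by-site interaction, the fits without batch 1 or of batches 2 or 3 alone, the fit with median UMIs as a covariate, the batch terms between sites and along the day, and the fit of all specimens for day 0 against day 5 were added after the data had been seen. Alternatives were TMM factors, limma 3.58.1 on logit shares, DESeq2 1.42.0, no filter on small clusters, cells with at least 500 genes, cells under 10% mitochondrial UMIs, coarser resolutions, batch terms, pairing by batch, and leaving out each specimen.

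Batches pair the specimens, since the authors' annotation names the batch of each and both genotypes were present in it. In day 12 myometrium/endometrium specimens, the deviations of log2 shares from the genotype mean correlated at 0.879, 0.673 and 0.867 over 51 clusters within the 3 batches. Between different batches they correlated at -0.765 to 0.307. Deviations from the mean of 3 specimens cancel out, so high correlations within batches push those between batches down, and the latter are no separate check. All are correlations across clusters, which are not independent replicates.

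The tests were checked on simulated cell counts with the real totals and mean shares. With no change, 3.60% of p-values were under 0.05 in the genotype comparison and 3.71% in the day trend. Every simulated specimen was drawn from the same mean shares, without differences between batches. These rates therefore do not cover the batch structure of the real specimens. Among 10 clusters changed 4-fold, 91.4% were recovered in the genotype comparison over all strata (a median of 49 clusters tested) and 49.6% in inter-implantation specimens (48). They were 67.4% in myometrium/endometrium specimens (49) and 40.1% between sites (49). Within single strata 0.753% of 4-fold and 27.1% of 16-fold changes were recovered (485 and 460 tests). In the day trend 7.97% of 4-fold and 56.1% of 16-fold changes over the sampled days were recovered (98 and 91 tests). Because shares sum to a fixed total, large changes in some clusters also produced calls in unchanged ones. In the day trend 71 of 359 calls were false at 16-fold and 873 of 1254 at 64-fold. In the genotype comparison of inter-implantation specimens 282 of 554 calls were false at 16-fold. At 4-fold, 45 of 300 calls were false in the genotype comparison over all strata, where 10.7% of p-values of unchanged clusters were under 0.05. False calls at 4-fold were 7 of 145 in inter-implantation specimens, 16 of 202 in myometrium/endometrium specimens and 14 of 128 between sites. Permutation tests used numpy 2.4.6 and scipy 1.17.1.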

Results

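Single cells were profiled from the uterus of control and Kdm6b cKO mice at sequential days of pregnancy. Tissue came either from between the implantation sites (inter-implantation) or from the myometrium and endometrium at the implantation site. The label of every pool gives the tissue as myometrium/endometrium, also where the pool held inter-implantation specimens. Here that name stands only for specimens of the implantation site. Inter-implantation specimens covered gestation days 5, 8, 12, 14, 16 and 18 with 1 specimen per genotype and day. Myometrium/endometrium specimens numbered 3 per genotype at day 12, 2 at day 18, and 1 at days 14 and 16. A further pair of inter-implantation specimens came from mice that were not pregnant and had received progesterone (0.2 mg per day over 3 days).

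The annotation held 107443 cells, 53170 from cKO and 54273 from control mice, in 7 pools of 13403 to 17111 cells. Specimens had 1769 to 5720 cells each. Cells had a median of 6061 UMIs and 1983 genes. The batches differed in depth, with a median of 3670 UMIs per cell in batch 1, 8082 in batch 2 and 6154 in batch 3. Cluster 1, whose cells had a median of 546 UMIs, made up 18.7% of the cells of batch 1, 0.578% of batch 2 and 1.51% of batch 3. Batch 1 held only myometrium/endometrium specimens. Inter-implantation specimens of days 12 to 18 were all in batch 2, and those of days 0, 5 and 8 all in batch 3.

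**Figure D1:**
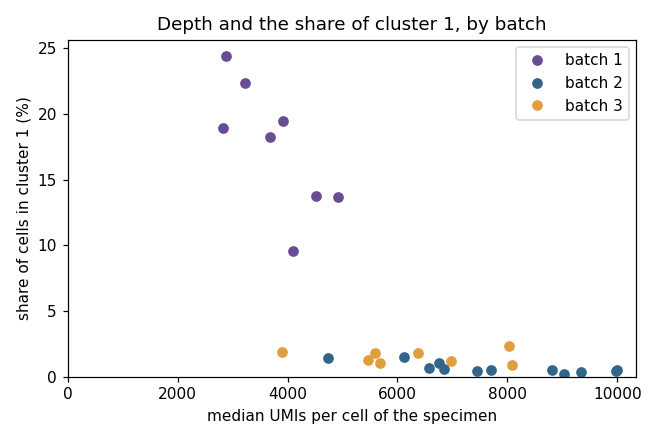
Each point is 1 of the 28 specimens, with the median UMIs per cell on the x axis and the share of its cells in cluster 1 (%) on the y axis, coloured by batch. The 8 specimens of batch 1 lie at 9.58% to 24.5%, above all specimens of batches 2 and 3.

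The first comparison asked which cell populations differed in abundance between cKO and control uteri. Cluster 13 took a larger share of cKO than of control cells. Its mean share was 3.56% ± 4.10 (SD, n = 13) in cKO and 0.793% ± 0.636 (SD, n = 13) in control specimens, and it was higher in cKO in 9 of 10 strata. The log2 difference was 1.84 (SE 0.46, adjusted p = 0.0362, edgeR). It was the only 1 of 51 clusters past the threshold, and 7 had an unadjusted p under 0.05. Among the 5 largest clusters, cluster 0 averaged 4.04% ± 3.93 (SD, n = 13) in cKO and 8.99% ± 8.65 (SD, n = 13) in control specimens, a log2 difference of -1.10 (SE 0.40) that did not pass (adjusted p = 0.209, edgeR). Clusters 1, 2, 3 and 4 did not pass either. No cluster passed at any of the 8 coarser resolutions (edgeR). The call of cluster 13 ended in 13 of the 26 fits that left out 1 specimen, with adjusted p between 0.0167 and 0.14 over all 26 (edgeR). It ended without either inter-implantation specimen of days 5, 12, 14, 16 or 18. Leaving out either specimen of such a day removes the day from the comparison, so the fits of a day are not separate checks. The call also ended without the day 12 myometrium/endometrium specimen of cKO in batch 2 or of control in batch 1. The last such fit was without the day 18 control myometrium/endometrium specimen of batch 1.

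The sites were then fitted separately, a choice made after the data had been seen. In inter-implantation specimens, clusters 13 and 28 were both higher in cKO on 6 of 6 days. Cluster 28 averaged 3.61% ± 2.16 (SD, n = 6) in cKO and 0.486% ± 0.855 (SD, n = 6) in control specimens, a log2 difference of 3.72 (SE 0.73, adjusted p = 0.00978, edgeR). Cluster 13 averaged 4.61% ± 4.75 (SD, n = 6) and 0.456% ± 0.318 (SD, n = 6), a log2 difference of 3.05 (SE 0.64, adjusted p = 0.00978, edgeR). At day 12 cluster 13 made up 13.6% of cKO cells (exact 95% interval 12.6 to 14.8) and 0.509% of control cells (0.233 to 0.964), and at day 18 it made up 2.67% (1.99 to 3.50) and 0.127% (0.0466 to 0.276). At day 8 it was at 1.27% (0.956 to 1.66) and 1.047% (0.745 to 1.43). Cluster 28 was at 2.65% (2.16 to 3.20) in cKO and 0.0565% (0.00143 to 0.315) in control at day 12, and at 6.78% (5.68 to 8.02) and 0.233% (0.116 to 0.416) at day 18. At day 8 it was at 3.44% (2.91 to 4.04) and 2.23% (1.78 to 2.75), and in the non-pregnant pair at 2.47% (2.02 to 2.98) and 2.60% (2.12 to 3.16). Within batch 2 (days 12 to 18) the log2 differences of clusters 28 and 13 were 4.94 (SE 0.71) and 4.07 (SE 0.60), and both passed (adjusted p = 3.27e-07 each, edgeR). Within batch 3 (days 5 and 8) they were 0.81 (SE 0.31, adjusted p = 0.0642, edgeR) and 0.70 (SE 0.51, adjusted p = 0.341, edgeR) and did not pass. These single-batch fits leave few residual degrees of freedom. Their p-values lean on a spread shared across clusters and were not checked by simulation. Cluster 0, among the 5 largest, was lower in cKO on 5 of 6 days. It was at 9.43% (8.45 to 10.5) in cKO and 4.36% (3.70 to 5.10) in control at day 5, at 1.32% (0.987 to 1.74) in cKO and 3.28% (2.499 to 4.22) in control at day 12, and at 6.14% (5.10 to 7.32) and 29.6% (28.3 to 30.9) at day 18; it did not pass over all days (log2 difference -1.60, SE 0.72, adjusted p = 0.217, edgeR) but did within batch 2 (-2.49, SE 0.57, adjusted p = 0.000645, edgeR). Of 48 clusters tested only 13 and 28 passed in edgeR, with 5 passing in limma and 8 in DESeq2. Without either day 5 specimen 4 passed, and without either day 8 specimen 5 passed (edgeR).

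In myometrium/endometrium specimens no cluster of 48 passed in edgeR, limma or DESeq2, and 1 had an unadjusted p under 0.05 in edgeR. At day 12 cluster 13 averaged 5.12% ± 4.76 (SD, n = 3) in cKO and 1.68% ± 0.673 (SD, n = 3) in control specimens. In batches 1, 2 and 3 it was at 1.53%, 10.5% and 3.31% in cKO against 0.906%, 2.16% and 1.96% in control. At day 14 it was lower in cKO, at 1.00% against 1.09%. The genotype effect was not shown to differ between sites, since 0 of 51 interaction terms passed in edgeR, 6 had an unadjusted p under 0.05, and the lowest adjusted p was 0.076, for cluster 28 (edgeR). DESeq2 called 1 and limma 0. Leaving out either day 8 inter-implantation specimen gave 3, and leaving out either of day 5, the batch 1 cKO or the batch 2 control myometrium/endometrium specimen of day 18 gave 1 (edgeR).

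**Figure D2:**
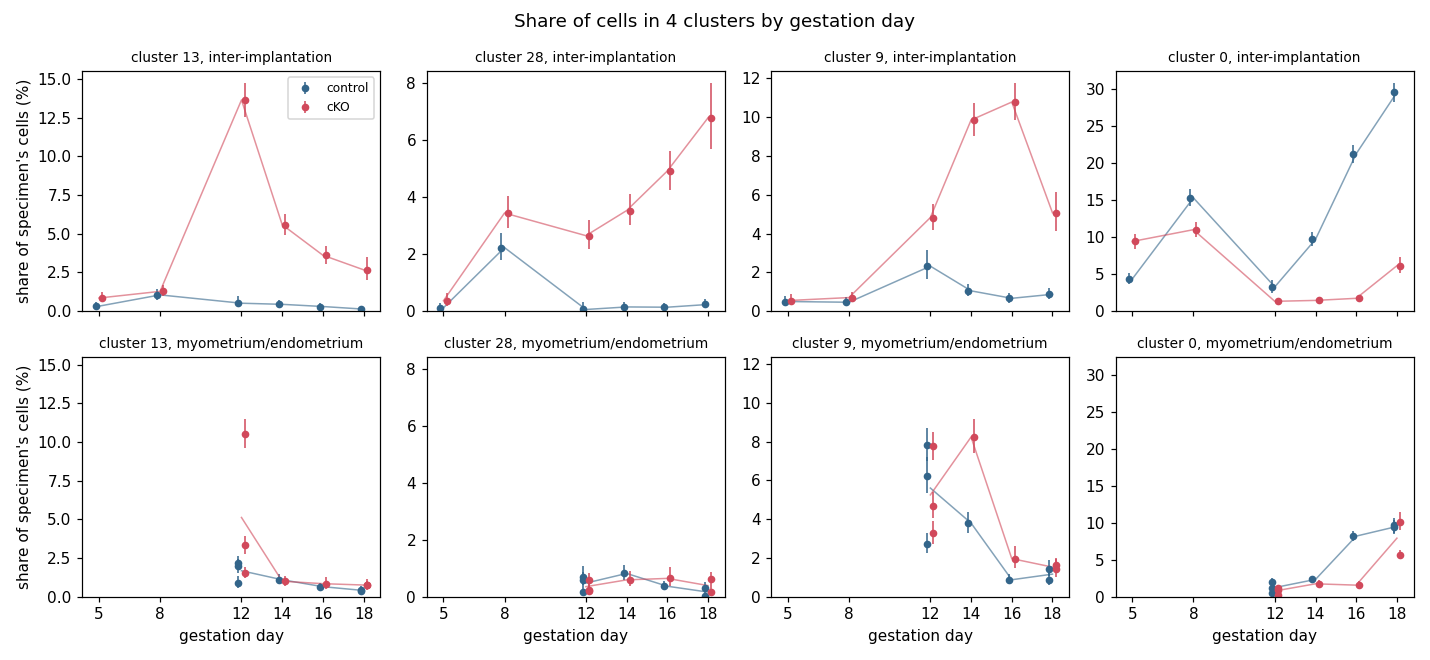
Share of each specimen's cells (%) in clusters 13, 28, 9 and 0 against gestation day, for inter-implantation (top) and myometrium/endometrium specimens (bottom). Points are specimens with exact 95% intervals of counting error and lines join daily means; cluster 28 in cKO inter-implantation specimens lies at 2.65% to 6.78% from day 12 on, against at most 0.233% in controls.

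Within single strata, no population passed among 510 tests in edgeR, limma or DESeq2, with 22 at an unadjusted p under 0.05 in edgeR. With each stratum and batch pair as a block, 39 tests passed (edgeR), among them 5, 7, 7 and 10 in inter-implantation specimens of days 12, 14, 16 and 18, 2 each in those of days 5 and 8, and 2 and 4 in myometrium/endometrium specimens of days 12 and 16. Day 12 of that site has 3 pairs, and clusters 14 and 17 were lower in cKO there (log2 differences -1.82, SE 0.55, and -1.64, SE 0.51) but higher at day 16 (2.95, SE 0.82, and 3.33, SE 0.87). The calls included cluster 28 at day 16, with a log2 difference of 5.14 (SE 0.98), and cluster 0 at day 16, with -3.62 (SE 0.70). The spread of the blocked fit rests on 3 residual degrees of freedom from the myometrium/endometrium pairs of days 12 and 18, and every inter-implantation stratum had 1 specimen per genotype, which is assumed to vary like those pairs.

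The next comparison set the sites against each other in control specimens of days 12 to 18. No cluster of 49 passed in edgeR or limma, 12 had an unadjusted p under 0.05 in edgeR, and DESeq2 called 11. Cluster 0 averaged 15.97% ± 11.8 (SD, n = 4) in inter-implantation and 4.75% ± 4.11 (SD, n = 7) in myometrium/endometrium specimens and was higher on 4 of 4 days, a log2 difference of 1.60 (SE 0.47, adjusted p = 0.0751, edgeR). Cluster 1 averaged 0.666% ± 0.524 (SD, n = 4) and 10.1% ± 9.34 (SD, n = 7), and only myometrium/endometrium specimens were in batch 1. With batch as a further covariate 4 clusters passed, with cluster 0 higher in inter-implantation specimens (log2 difference 1.21) and clusters 5, 13 and 17 lower (log2 differences -1.53, -1.95 and -2.61). Within batch 2 alone, with both genotypes, 0 passed in edgeR, with 5 at an unadjusted p under 0.05. Without the control inter-implantation specimen of day 12 there were 7 calls, and without the batch 3 control myometrium/endometrium specimen of day 12 there were 6 (edgeR).

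Along gestation, the slope of each cluster's share on the day was tested in control tissue. In inter-implantation specimens this slope is mixed with a step between batches, so the calls there need not reflect the day. In inter-implantation specimens 17 of 48 clusters passed, 6 rising and 11 falling. Large changes elsewhere can produce calls in unchanged clusters, so a single call among these need not be a change of its own. With simulated 64-fold changes 873 of 1254 calls were false in this way. Cluster 3, among the 5 largest, rose by a log2 slope of 0.51 per day (SE 0.07, adjusted p = 0.00168, edgeR), from 0.116% at day 5 (exact 95% interval 0.0317 to 0.297) to 14.6% at day 18 (13.6 to 15.6). Cluster 4 rose from 0.378% (0.201 to 0.645) to 6.26% (5.59 to 6.99) and cluster 20 from 0.0581% (0.00704 to 0.21) to 3.24% (2.75 to 3.78). Clusters 24, 35 and 49 also rose. Cluster 11 fell by 0.28 on the log2 scale per day (SE 0.05, adjusted p = 0.00475, edgeR), from 12.2% (11.1 to 13.4) to 1.12% (0.841 to 1.46). Cluster 18 fell from 9.62% (8.66 to 10.7) to 0.339% (0.194 to 0.549) and cluster 31 from 4.74% (4.05 to 5.502) to 0.0846% (0.0231 to 0.217). Clusters 7, 26, 33, 42, 45, 51, 52 and 60 fell as well, but the fall of cluster 60 rests on the day 5 specimen (1.77%, 1.36 to 2.27), with 0 cells in the other 5. In myometrium/endometrium specimens 5 of 48 passed between days 12 and 18. Cluster 0 rose by a log2 slope of 0.52 per day (SE 0.12, adjusted p = 0.0142, edgeR), from 1.23% ± 0.734 (SD, n = 3) at day 12 to 9.51% ± 0.184 (SD, n = 2) at day 18. Cluster 35 rose, and clusters 9, 17 and 25 fell.

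Days 5 and 8 of the inter-implantation series came from batch 3 and the later days from batch 2, so the slope and the batch step are mixed. With batch as a covariate 27 slopes passed, 12 of them among the 22 above; cluster 3 and the myometrium/endometrium slope of cluster 0 were among these, and clusters 4, 11 and 20 were not. Within batch 2 alone 22 passed in inter-implantation specimens, 6 of them among the 17 above, namely clusters 7, 18, 24, 31, 35 and 49, while cluster 3 had an adjusted p of 0.058 (edgeR). With 1 of the 4 specimens left out 2 to 3 of these 6 passed, and none passed in all 4 such fits (edgeR). The myometrium/endometrium slopes of clusters 9, 17 and 25 also passed with the batch term, and that of cluster 35 did not (0.47, SE 0.19, adjusted p = 0.107, edgeR). Cluster 35 was at 3.64% (3.07 to 4.30) in batch 1 and 0.341% (0.176 to 0.595) in batch 2 at day 18, against 0.155% (0.0569 to 0.337) to 0.248% (0.119 to 0.456) at day 12. Without batch 1 only 3 of these specimens remained, so calls lost there say little, and the slopes of clusters 0, 9, 17 and 25 were 0.49, -0.43, -0.29 and -0.31. Without the control day 5 specimen 6 slopes passed over both sites.

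**Figure D3:**
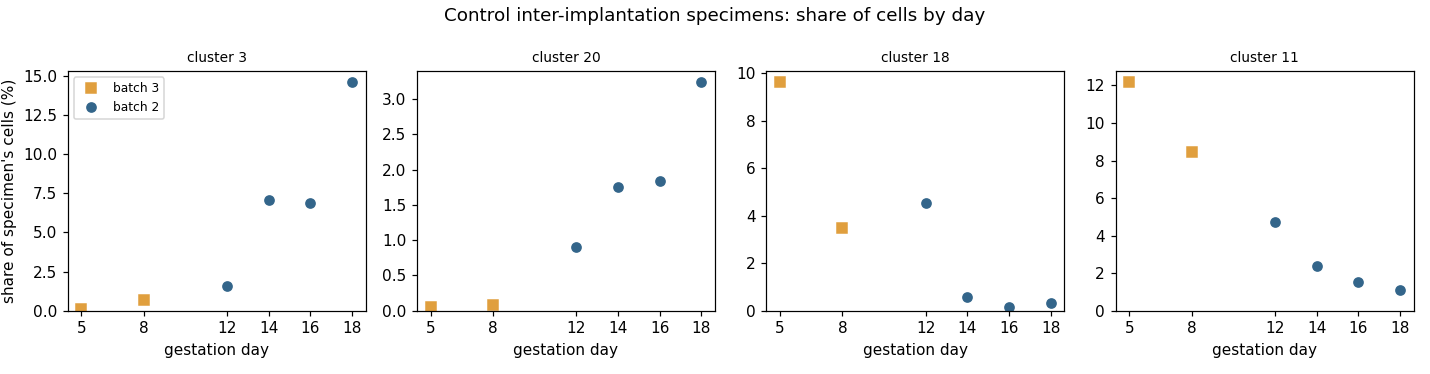
Share of cells (%) in clusters 3, 20, 18 and 11 against gestation day in the 6 pregnant control inter-implantation specimens, 1 point each, with squares for batch 3 and circles for batch 2. Cluster 3 climbs to 14.6% and cluster 11 drops to 1.12% at day 18.

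Non-pregnant progesterone-treated and day 5 pregnant inter-implantation tissue were compared as values, with 1 control specimen each and no replicate check. Their compositions over 44 clusters differed by 35.6% of cells (multinomial bootstrap 95% interval 34.0 to 38.2). Cluster 0 was at 13.9% (95% interval 12.8 to 15.0) in the non-pregnant and 4.36% (3.70 to 5.10) in the day 5 specimen, and cluster 2 at 10.1% (9.15 to 11.1) and 6.13% (5.35 to 6.99). Cluster 1 was at 1.81% (1.41 to 2.29) and 1.86% (1.44 to 2.37), cluster 3 at 0.447% (0.26 to 0.714) and 0.116% (0.0317 to 0.297), and cluster 4 at 0.499% (0.301 to 0.778) and 0.378% (0.201 to 0.645). These intervals are exact and, like the bootstrap, cover counting error only. In the cKO specimens cluster 2 was at 7.83% (7.03 to 8.69) at day 0 and 14.1% (12.9 to 15.3) at day 5. A fit of all 28 specimens, added after the data had been seen, called 0 of 51 clusters in edgeR, with 5 at an unadjusted p under 0.05, while limma called 1 and DESeq2 called 2.

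Cell quality did not differ detectably between genotypes. The specimen medians averaged 6332 ± 2273 UMIs (SD, n = 13) in cKO and 6087 ± 2296 (SD, n = 13) in control specimens, higher in cKO in 7 of 10 strata (two-sided permutation test, p = 0.616, adjusted p = 0.616). Median genes averaged 1976 ± 420 and 1909 ± 419 (permutation test, p = 0.375, adjusted p = 0.616), and median mitochondrial percent 2.70 ± 0.549 and 2.67 ± 0.422 (permutation test, p = 0.613, adjusted p = 0.616; SD, n = 13 each). Phase calls averaged 10.0% ± 4.15 S in cKO and 10.1% ± 4.19 in control specimens (permutation test, p = 0.886, adjusted p = 0.886; SD, n = 13 each). G2M calls averaged 14.1% ± 4.98 and 12.8% ± 5.998 (permutation test, p = 0.204, adjusted p = 0.408; SD, n = 13 each). The calls are scores of unequally deep cells and are not read as cycling.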

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

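The tests of neighbouring clusters, of median UMIs, of implantation-site tissue, of cluster 1 and of the day trend, and the splits that kept batch pairs, were chosen after the results were seen. No pool stood apart from the others in any of 6 measures by the gap between neighbouring values. Each batch held at least 2 pools, so this gap could not flag a whole batch. The 2 pools of batch 1 had median UMIs of 3582 and 3792, against 5626 to 8397 in the others. No genotype effect on a cluster, a quality measure or a phase differed between sites at an adjusted p under 0.05 (edgeR for clusters, with 6 at an unadjusted p under 0.05 and 1 call in DESeq2; permutation tests for the others).

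With the log2 median UMIs of the specimen as a covariate, the excess of clusters 13 and 28 in cKO inter-implantation specimens had log2 differences of at least 3.102 (SE 0.70, adjusted p = 0.0222, edgeR). This argues against the specimens' median UMIs as the whole cause, although the day 12 medians were 9978 UMIs in cKO and 4733 in control. That median depends in part on the composition itself. Cells of clusters 13 and 28 had medians of 9609 and 14955.5 UMIs, against 6061 over all cells. Whether depth shifts the assignment of cells to clusters was not tested. Keeping cells of at least 500 genes (smaller difference 3.06) removed only 0.133% and 4.08% of the cells of clusters 13 and 28 and does not test depth. In cKO inter-implantation specimens of days 12 to 18 cluster 28 made up at least 2.65% of cells, against at most 0.815% (SD 0.244, n = 14) in myometrium/endometrium specimens. Its log2 difference between cKO specimens of the sites, with day and batch as terms, was 4.33 (SE 0.61, adjusted p = 6.47e-05, edgeR). This argues against admixed myometrium/endometrium of the implantation site, while other tissue of that site was not among the specimens. The fit had 4 residual degrees of freedom, so its p-value leans on a spread shared across clusters, and at days 14 and 16 the sites share no batch. For cluster 13 the difference was 0.86 (SE 0.54, adjusted p = 0.366, edgeR), so such tissue stays open. The shares of cluster 13 were 13.6%, 5.58%, 3.61% and 2.67% at days 12, 14, 16 and 18. They lay above the highest myometrium/endometrium shares of 10.5%, 1.09%, 0.842% and 0.757%. The coarse cluster that holds cluster 13 differed by a log2 value of -0.14 (SE 0.32), so its cells may have been divided differently among the clusters of coarse cluster 0, whereas the one that holds cluster 28 (log2 difference 3.74) consists of 98.9% the same cells, which does not decide whether cells moved in from other clusters. Over all strata 2 of 100 splits, the real one included, called as many clusters as the real 1 (highest other 1). The same 2 of 100 was found when genotypes were exchanged only within the 13 batch pairs (highest other 1). Both shares lie under 0.05, which argues against chance only for this count of 1 at resolution 2. No cluster passed at the 8 coarser resolutions, and the call ended in 13 of the 26 fits without 1 specimen. In inter-implantation specimens 2 of 32 splits called as many as the real 2 (highest other 2, from exchanging the day 8 pair), so chance is not excluded there. An effect of the genotype stays open.

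The excess of cluster 1 in batch 1 was weighed as a matter of site or of batch. In myometrium/endometrium specimens of days 12 and 18 its share was at most 2.34% in batches 2 and 3 and at least 13.7% in batch 1, which argues against the site and is consistent with a difference between library batches. No biological explanation was tested. The same batch bears on the comparison of sites: with a real count of 0 clusters, the 48 splits of the control specimens within days (48 with at least as many) say nothing about chance, and the highest other count, 12, came from the split that set the 4 control specimens of batch 1 against all others. Within batch 2 alone, with both genotypes, 0 passed, and with batch as a covariate 4 did (edgeR).

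The day trend in control inter-implantation specimens was set against a step between batches 3 and 2, which hold the early and the late days. Of the 17 called clusters 6 also passed within batch 2 with their sign kept (edgeR), and 2 to 3 did with 1 of its 4 specimens left out. At most 1 did in 100 simulations with a step and no slope, which were not refitted without a specimen. Those simulations drew clusters independently. In 90 of the 100 a cluster with cells in batch 2 was called over all days. The median in these was 4 calls and the most was 20, against 16 such clusters in the real specimens. Among clusters tested within batch 2, those not called over all days passed about as often as the called ones. The overlap therefore does not decide whether the step is the whole cause of the trend. For single clusters slope and step cannot be told apart, since 0 of the 17 passed within batch 2 both with all specimens and without each.

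Between genotypes in myometrium/endometrium specimens the real count was 0, so the 100 splits (100 with at least as many) say nothing about chance. The highest other, 6, points to a structure of the specimens, since its arm held all 4 specimens of batch 2, and the highest was 0 in the 64 splits that exchanged genotypes only within batch pairs. The 10 splits of the 6 day 12 specimens are too few for a share under 0.05 (real 0, highest other 9).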

How the results depend on the processing

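The fits without batch 1, with low-UMI clusters left out, of single sites, of the interaction and of batch 2 alone, of batch 3 alone, of coarse cluster 0 alone, with median UMIs as a covariate, without the day 12 myometrium/endometrium specimens of batch 3, of the day trend in both genotypes, of day 0 against day 5 in all specimens, and with batch terms between sites or along the day were added after the data were seen. The others were planned. The minimum of cells per specimen removed no specimen. Tests of non-pregnant against day 5 specimens with TMM, limma or DESeq2, or with a specimen left out, were not run in the planned form, since each arm held 1 specimen. The genotype count over all strata was 1, cluster 13, in each of the other tools and filters, with batch 1 left out (adjusted p = 0.0173, edgeR) and with the replicate block (1, adjusted p = 0.0313, edgeR), but 0 at each of the 8 coarser resolutions, and 0 to 1 with single specimens left out. Within strata the replicate block gave 39 against 0. Simulations with no genotype effect used a chosen batch effect with an SD of 1 on the natural log scale. In these 0.0617% of p-values were under 0.05 without the block and 5.22% with it. The unblocked fit thus called too little at that setting, and 2 of 20 blocked simulations made a call. All strata were drawn with the same dispersion. Whether inter-implantation specimens vary like the replicated pairs was therefore not tested. The block changed no other call.

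Between sites the count of 0 became 1 with TMM, 11 with DESeq2, 1 with low-UMI clusters left out, 4 with day and batch as covariates and 0 to 7 with single specimens left out, with 7 without the control inter-implantation specimen of day 12. Cluster 3 reversed to -0.16 with cells of at least 500 genes, -0.25 without low-UMI clusters, -0.71 without batch 1, -0.21 with the batch term and -0.94 in batch 2 alone. Cluster 4 reversed to -0.12, -0.20, -1.14, -0.90 and -0.89 in the same order. Cluster 1 reversed to 0.15 without batch 1, 0.0703 with the batch term and 0.22 in batch 2 alone. None of the 3 had passed.

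The day trend ranged from 6 to 26 calls with single specimens left out, with 10, 11, 7 and 4 in batch 2 alone without its inter-implantation specimen of day 12, 14, 16 or 18, and cluster 51 reversed to a slope of 0.0105 with batch as a covariate. In inter-implantation specimens alone the genotype count of 2 became 5 with limma, 8 with DESeq2, 3 with no filter, 3 with cells of at least 500 genes, 3 at resolution 0.2, 10 with median UMIs as a covariate, 7 in batch 2 alone, 7 in batch 3 alone (none of them 13 or 28) and 2 to 5 with single specimens left out. The interaction count of 0 became 1 with DESeq2, 1 at resolution 0.2 and 0 to 3 with single specimens left out. The fit of non-pregnant against day 5 in all specimens gave 1 with limma, 2 with DESeq2, 2 with cells of at least 500 genes, 2 with cells under 10% mitochondrial and 1 with low-UMI clusters left out, against 0. The median UMI difference ranged from -116 to 791 and the mitochondrial difference from -0.0293 to 0.156 with single specimens left out, with no call; the negative values came without either inter-implantation specimen of day 12 and without either myometrium/endometrium specimen of day 16. Depth limits these results in that cells could not be thinned to equal UMIs. The cause of these changes was not tested.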

Other observations

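The test of resemblance to an earlier day was chosen after the shares were seen, and so were the clusters named next. Cluster 60, the smallest of the 61, held 67 cells, and 61 of them came from the control inter-implantation specimen of day 5, where they made up 1.77% of the cells (exact 95% interval 1.36 to 2.27). The cKO specimen of that day gave 2 of them. Its cells had a median of 37771 UMIs, and with 1 specimen per genotype at that day the difference has no replicate check. Clusters 39 and 40, in which 65.6% and 94.7% of cells carried a G2M call, made up 1.63% (1.251 to 2.08) and 2.42% (1.95 to 2.96) of the non-pregnant control specimen. At day 5 cluster 39 had 0 of 3440 control cells (exact upper limit 0.107%), and cluster 40 was at 0.0581% (0.00704 to 0.21). Cluster 40 averaged 0.781% in cKO and 0.359% in control specimens, and its stratum mean was higher in cKO in 10 of 10 strata of pregnant specimens. This did not pass the adjustment (adjusted p = 0.302, edgeR). By batch pair it was lower in cKO in myometrium/endometrium of day 12 in batches 1 and 3 and of day 18 in batch 2. In the non-pregnant pair it was also lower in cKO, at 0.742% (0.505 to 1.052) against 2.42%.

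Whether cKO inter-implantation specimens of days 14 to 18 resemble an earlier control day was tested as a hypothesis. The control specimen of batch 2 with the least dissimilar composition was of an earlier day for 2 of the 3, which does not decide it. The day 18 cKO specimen differed by 30.9% of cells from the day 14 control and by 50.6% from the day 18 control. At day 16 the values were 45.5% for day 14 and 46.3% for day 16, and at day 14 the nearest was day 14 itself, at 41.7%. Each value compares a pair of specimens, with no replicate.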
